A study of Arabidopsis thaliana with 2 samples.

How the data were processed

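Whole-genome bisulfite sequencing, in which unmethylated cytosines are converted and methylated cytosines are read as cytosine, was analysed for 2 libraries of Arabidopsis thaliana (Columbia-0 background). Both came from aerial tissue of a line named TEmob. Per the labels' protocols, its seeds had been germinated on α-amanitin and 40 µM zebularine and kept at 37 °C, and the line was then crossed to a cenh3 CENH3-tailswap plant, which yields haploid offspring. A diploid line was recovered after colchicine treatment. Zebularine is an inhibitor of DNA methyltransferases and α-amanitin one of RNA polymerase II. DNA was extracted from 100 mg of tissue pooled from 3 plants of 4 weeks, in generation T4 per the sample labels (the series design text names T3), and libraries were made with the Accel-NGS Methyl-Seq kit. The labels number the libraries replicate 1 and replicate 2 and do not say whether the pools came from separate plants, so the spread between them may be technical.

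The deposited values are counts: for each cytosine, the number of methylated and of unmethylated read calls, in 1 table per library and sequence context (CG, CHG and CHH, where H is A, C or T). Per the submitters' processing notes, Bismark and the genome build TAIR10 were used. The Bismark version, read trimming, quality filters and duplicate removal are not given in the sources used here, so the calls may include copies of 1 molecule made by PCR, and reads with several possible positions may have been dropped. The tables cover chromosomes 1 to 5 and list 42859750 cytosines, including those with 0 reads. Chloroplast and mitochondrial cytosines were not analysed here. The chloroplast background planned for the test of single cytosines was therefore replaced, after the data had been seen, by the CHH level over 14 housekeeping genes (0.647% ± 0.00350, SD, n = 2).

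Gene names, types and bounds came from an NCBI RefSeq gene table of assembly TAIR10.1. All 106 loci of the fixed lists were matched in it. Because its assembly is named differently from the build of the counts, the bounds were checked against the bases in the counts. A motif shared by transfer RNA genes was looked for on both strands and was held by 239 of 625 such genes. In 238 of these it lay at the same distance of 11 bp from the annotated gene end, read along the strand of the motif. Coordinates printed here are those of the count tables. Strand, exons, introns, untranslated regions and transposon annotation were not analysed here. Transposable elements were represented by 4843 pseudogene loci (3917 pseudogenes and 926 transcribed pseudogenes), a class that mixes transposon genes with disabled copies of ordinary genes. Profiles around genes were mirrored over both gene ends.

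The methylation level is the percent of methylated calls among all calls of a context. Values are the mean ± SD of the 2 libraries (n = 2) unless a library is named. Wilson 95% intervals were computed for single libraries, and they cover counting error only. No test between groups was possible with 1 group, and the smallest 2-sided p that a paired exact test can give with 2 libraries is 0.5. Pericentromeres were set as 6 Mb windows, at 12 to 18 Mb of chromosome 1, 1 to 7 Mb of chromosomes 2 and 4, 11 to 17 Mb of chromosome 3 and 9 to 15 Mb of chromosome 5. Each protein-coding gene with at least 20 CG sites covered by at least 4 reads was tested in each library and context with a 1-sided exact binomial test. The background was the level over all protein-coding gene bodies of that library (13.4% and 13.7% in CG, 1.42% and 1.39% in CHG, 0.884% and 0.889% in CHH for replicates 1 and 2), with Benjamini-Hochberg adjustment at 0.05. Genes past the test in CG alone were called gene body methylated, genes past it in CHG or CHH TE-like, and genes past no test with CG under the background unmethylated. Genes with the same call in both libraries were kept. Unmethylated here thus means below the average gene and not free of methylation.

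Fixed gene lists were compared with all other classified genes by a 2-sided Fisher's exact test, adjusted over 10 tests. Single cytosines with at least 4 reads were tested with the same binomial test. Replicates 1 and 2 were compared in 100 bp windows with at least 4 cytosines and 20 reads in each library by a 2-sided Fisher's exact test on calls. An adjusted p under 0.05 and a difference of at least 35 (CG), 20 (CHG) or 15 (CHH) percentage points were required. These tests treat calls from the same DNA fragment as independent, which makes their p-values too small. Relative depth is the mean number of calls per cytosine of a locus over the median of that value in protein-coding genes. For the 100 bp depth windows, it is the mean over the median window, and a stretch of windows is given by its median. Bases were read back from the trinucleotides in the counts to find the start codon of PHE1 and 1 coding motif of RANGAP1.

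Replicate 1 held 618848322 calls and replicate 2 639642237, a mean depth of 14.4 and 14.9 calls per cytosine and a median of 13 and 14. At least 4 reads covered 96.4% and 97.0% of cytosines. Cytosines over 100 reads made up 0.109% and 0.107% of sites and carried 8.15% and 7.16% of calls. The levels were recomputed without them, an alternative added after seeing the data.

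The groups, tests, gene lists and rule for named genes were fixed before the data were examined. Named were up to 6 members of each list (TE-like members first, then the highest CG), all ONSEN and other fixed mobile elements, and the 10 pseudogene loci with the most CG sites among those under 10% CG. The 10 loci of highest relative depth, the 10 loci with the largest CG difference between replicates past the test, the 10 TE-like genes of highest CHG and the 5 gene body methylated genes of highest CG were named as well. The rule also asked for the 5 loci of lowest depth, but 179 loci had 0 reads in both libraries and could not be ranked. Names outside this rule are said to be chosen after their values were seen.

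The code was tested on simulated counts drawn from the real depths. Among 26339 simulated genes, 200 of 200 gene body methylated and 200 of 200 TE-like genes were recovered, with 0 false calls. All unchanged genes had the same low level, far below the changed ones, so this outcome was largely fixed by the settings. Of 200 windows raised by 50 points in CG, 98.0% were found, with 1 false call among 677933 windows. Of 200 raised by 35 points in CHG, 83.0% were found among 734858 windows, and of 200 raised by 30 points in CHH, 99.0% among 1173512, with 0 false calls in either. Simulated calls were independent, unlike real calls on shared fragments, so these numbers check the code and do not give error rates for the real data. The alternatives were the coverage minimum, weighting, pericentromere width, thresholds, window size, depth scaling, background and each library alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.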

Results

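DNA methylation was measured at single cytosines in aerial tissue of the TEmob line, a Columbia-0 derivative in which transposons had been mobilised by chemical treatment and heat. The 2 libraries form a single group of replicates, with 618848322 and 639642237 methylation calls. The series examines the consequences of transposon mobilisation, and the tissue measured here gives the methylation state of the line itself. No untreated plants were analysed here, so each comparison is between sequence contexts, regions or genes of the same libraries, and gains or losses relative to wild type could not be tested.

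CG sites were the most methylated in the nuclear genome, followed by CHG and CHH sites. Levels were 22.9% ± 0.0891 in CG, 6.83% ± 0.108 in CHG and 2.17% ± 0.0278 in CHH (SD, n = 2). In CG, replicate 1 stood at 22.9% (Wilson 95% interval 22.9 to 23.0) and replicate 2 at 22.8% (22.8 to 22.8). The differences between contexts were many times the spread between replicates. Over 14 housekeeping genes, measured in the same way, the levels were 7.89% ± 0.501 in CG, 0.720% ± 0.0664 in CHG and 0.647% ± 0.00350 in CHH, and the CHH value served as the background. In the test of single cytosines against this background, 29.3% ± 0.0875 of CG, 14.5% ± 0.108 of CHG and 3.25% ± 0.00403 of CHH sites were called methylated. The level at called sites was 66.4% ± 2.06 in CG, 35.6% ± 1.23 in CHG and 15.5% ± 0.505 in CHH. Against a fixed background of 2%, the CHH share was 1.97%.

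Methylation was concentrated around the centromeres. In CG, pericentromeres stood at 49.9% ± 0.776 and chromosome arms at 12.3% ± 0.0671, a difference of 37.6 ± 0.709 percentage points. In CHG the levels were 21.4% ± 0.297 and 2.15% ± 0.0329, and in CHH 4.93% ± 0.000572 and 1.13% ± 0.00157. The CG difference was 49.4 ± 0.166 points on chromosome 5, 45.7 ± 0.0995 on chromosome 4, 42.1 ± 0.0495 on chromosome 2 and 40.6 ± 0.426 on chromosome 1. On chromosome 3 it was 26.4 ± 1.40 points, but this low value rests on cytosines of very high depth. Without cytosines over 100 reads, an alternative chosen after seeing the data, the difference was 49.9 ± 0.311 on chromosome 3 and from 40.0 to 47.4 on the others. The window of 200 kb centred at 14.1 Mb of chromosome 3 had a CG level of 18.5% and 19.8% in replicates 1 and 2, against 80.5% and 82.3% in the window centred at 13.9 Mb. AT3G41762, annotated as protein-coding in the pericentromere of chromosome 3, had the highest relative depth of all loci, at 366 and 306 times the median gene, with a CG level of 20.5% ± 0.784. On chromosome 2, the window centred at 3.3 Mb had a CG level of 24.7% and 24.1%. It holds AT2G07688, which had 9.66 and 9.09 times the depth of the median gene and a CG level of 22.2% ± 0.833. Whether high depth lowers the level of this window was not tested. On chromosome 4, windows centred at 1.7 to 2.1 Mb, over the heterochromatic knob, reached 70.3% to 77.5% in CG, the window centred at 2.5 Mb was at 27.8% and 28.7%, and the one at 2.9 Mb at 72.0% and 72.7%, all inside the span counted here as pericentromere.

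**Figure D1:**
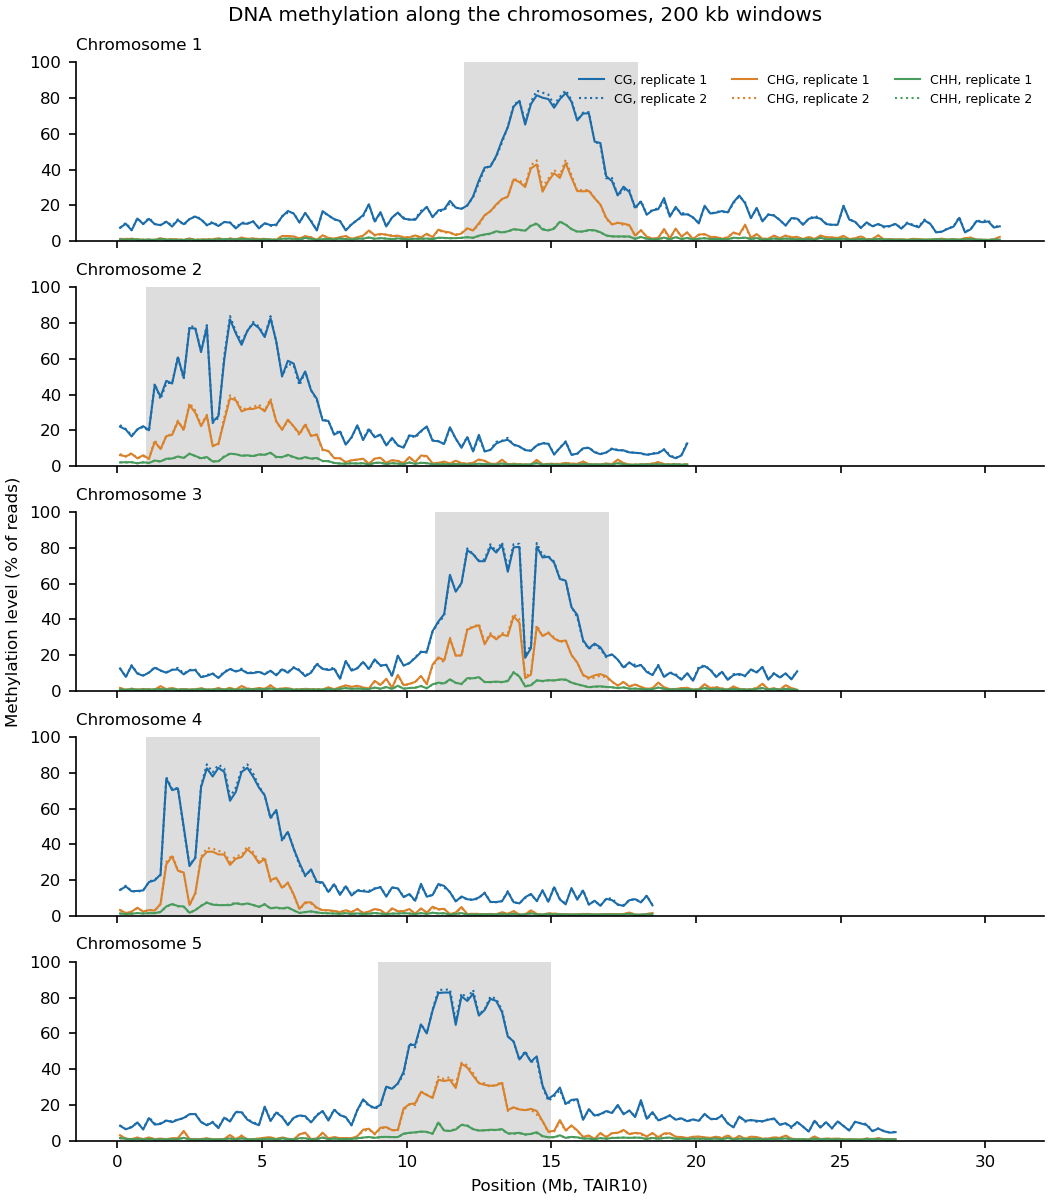
Methylation level (percent of calls, y axis) in 200 kb windows along chromosomes 1 to 5 (x axis, Mb, TAIR10) for CG, CHG and CHH, with replicate 1 as solid and replicate 2 as dotted lines and the 6 Mb pericentromeres shaded. CG rises from about the arm level of 12.3% to above 80% next to the centromeres, with a drop to 18.5% at 14.1 Mb of chromosome 3.

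Pseudogene loci, the class that holds the annotated transposon genes, carried far more methylation than protein-coding genes in every context. CG levels were 71.3% ± 0.349 over pseudogene loci and 13.6% ± 0.192 over protein-coding gene bodies, 57.7 ± 0.156 points apart. In CHG the levels were 35.8% ± 0.647 and 1.41% ± 0.0171, and in CHH 7.21% ± 0.0437 and 0.889% ± 0.00339. The 1 kb flanks of protein-coding genes stood at 13.6% ± 0.150 in CG, 5.24% ± 0.0846 in CHG and 1.89% ± 0.00415 in CHH. RNA genes were at 18.8% ± 0.203 in CG, a value weighted to cytosines of very high depth (12.4% without those over 100 reads, a limit set after seeing the data). The remaining intergenic sequence was at 48.1% ± 0.484. In 14444 protein-coding genes of at least 2 kb, CG was lowest in the first 100 bp inside the gene ends, at 3.14% ± 0.0204, and reached 36.8% ± 0.164 in the bin that begins 1900 bp inside. In 2127 pseudogene loci of that length, the same 2 bins stood at 74.7% ± 0.203 and 74.3% ± 0.579. Each end was followed only to the middle of the locus, so bins more than 1 kb inside hold only the longer loci. The rise inside genes therefore mixes position with gene length. Exons, introns and untranslated regions were not analysed here.

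**Figure D2:**
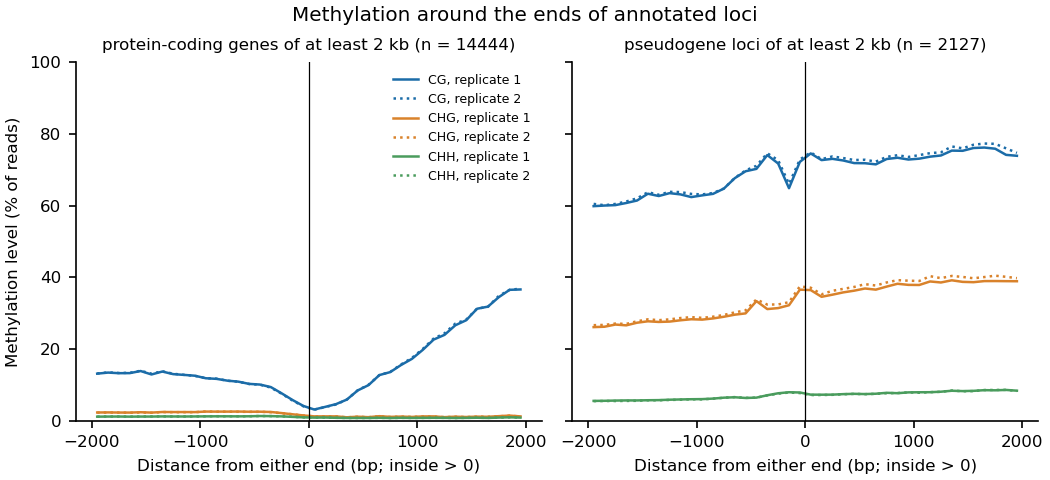
Methylation level (percent of calls, y axis) in 100 bp bins from 2 kb outside to 2 kb inside the ends of protein-coding genes (left) and pseudogene loci (right), with both ends of each locus overlaid (x axis, bp), for CG, CHG and CHH in replicate 1 (solid) and replicate 2 (dotted). Genes show a CG minimum of 3.14% at their ends, while pseudogene loci lie between 60.1% and 76.8% in every CG bin. Bins more than 1 kb inside hold only the longer loci.

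The mobile elements fixed for this line were densely methylated in both libraries. ONSEN (ATCOPIA78), a heat-activated copia retrotransposon, had a median CG level of 82.4% ± 1.63 over its 8 copies, from 80.6% to 88.5%. CHG had a median of 34.9% ± 2.12 and a range from 12.0% in AT3G32415, the copy in the pericentromere of chromosome 3, to 51.9% ± 8.99 in AT5G13205. CHH had a median of 15% ± 0.440, from 5.24% ± 0.0494 in AT3G32415 to 22.1% ± 0.812 in AT5G13205. The lowest CHH level among the 7 copies in chromosome arms was 14.2% ± 0.511, in AT1G21945, followed by AT1G58140, AT3G61330, AT3G59720, AT1G48710 and AT1G11265 (19.7% ± 0.170). The neighbouring loci AT2G23500 and AT2G23480 of the DNA transposon VANDAL21 had CG levels of 88.3% ± 2.09 and 88.8% ± 0.754, with CHH at 14% in both. EVADE (AT5G17125), a copia element known to transpose when methylation is lost, and its relative ATR (AT1G34967) had CG at 72.6% ± 0.101 and 78.9% ± 3.35, but CHG at only 10.5% ± 1.01 and 11.3% ± 2.87. CACTA1 (AT2G12210) stood at 80.3% ± 1.77 in CG and 46.2% ± 1.54 in CHG, the retrotransposon Ta3 (AT1G37110) at 79.0% ± 0.781 and 51.7% ± 2.52, and the MuDR element AT4G08680 at 87.7% ± 1.54 and 36.7% ± 0.544. Reads of near-identical copies may have been dropped, so the levels may rest on the distinguishable parts of these copies. In AT1G11265, 25 and 24 of 236 CG sites had at least 4 reads.

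**Figure D3:**
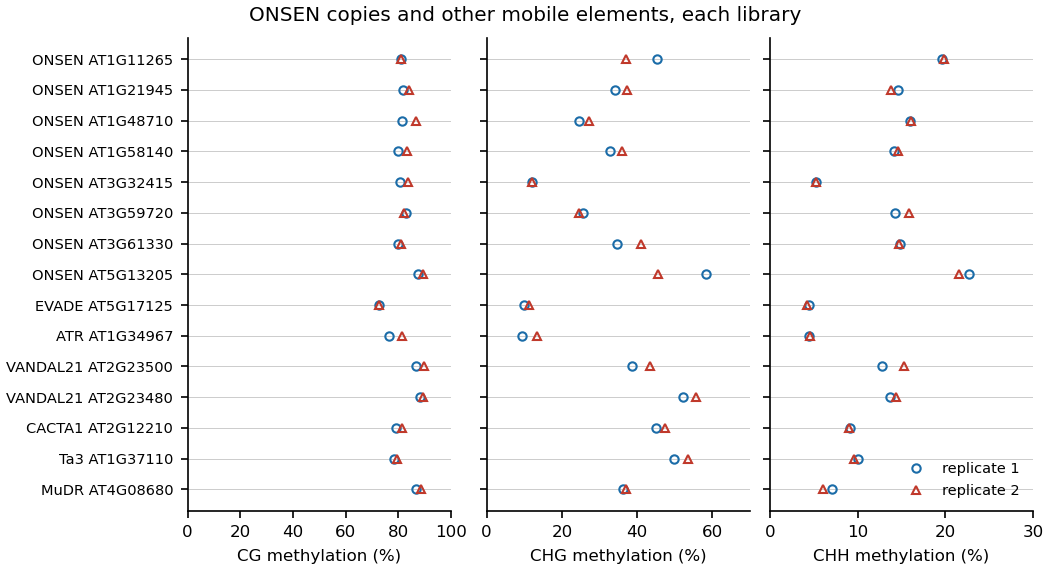
Methylation level (percent of calls, x axes) of 8 ONSEN copies and 7 loci of other mobile elements (y axis) in CG, CHG and CHH, with replicate 1 as circles and replicate 2 as triangles. CG lies between 72.6% and 88.8% on average in all 15, while CHG and CHH are lowest in EVADE, ATR and the ONSEN copy AT3G32415.

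Pseudogene loci fell into a large methylated and a smaller unmethylated set. Of 4306 loci tested, 3416 (79.3%) had a CG level above 70% in both libraries, and 580 (13.5%) were under 10% in both libraries. The share under 10% was 42.5% in chromosome arms (399 of 938) and 5.37% in pericentromeres (181 of 3368). Among transcribed pseudogenes it was 56.5% (391 of 692), and among the others 5.23% (189 of 3614). The loci under 10% had median levels of 0.747% ± 0.0122 in CG, 0.621% ± 0.0173 in CHG and 0.664% ± 0.0160 in CHH, and the other loci medians of 84.1% ± 1.32, 38.6% ± 1.18 and 7.40% ± 0.0737. Pooled over all calls of the loci under 10%, CG sites were higher than their median locus, from 1.45% ± 0.0712 (CGT) to 2.44% ± 0.0815 (CGC). The 10 with the most CG sites were AT3G31005, AT3G10100, AT5G28635, AT3G60935, AT3G60930, AT1G46552, AT3G06433, AT5G28145, AT2G23330 and AT4G20730. All but AT3G31005 had CHG and CHH under 1%. AT3G31005, in the pericentromere of chromosome 3, had CG at 6.22% ± 0.593, CHG at 5.68% ± 0.458 and CHH at 3.74% ± 0.481. In each context it was above the median of the loci under 10%. AT3G06433 had a relative depth of 1.91 ± 0.186.

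**Figure D4:**
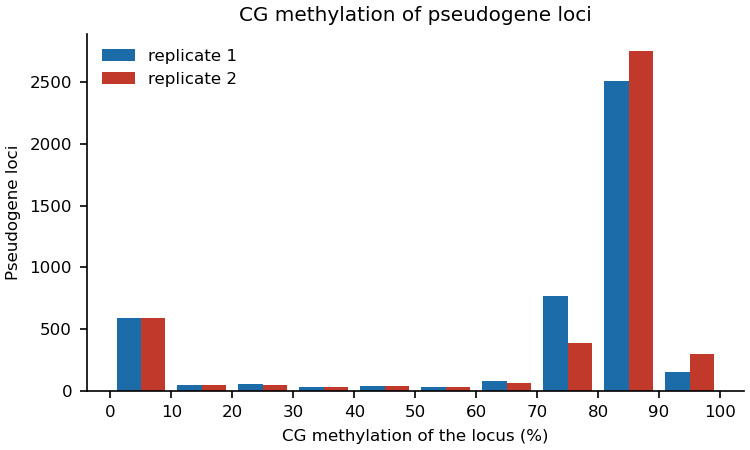
Number of pseudogene loci (y axis) by CG methylation level in bins of 10% (x axis) in replicate 1 and replicate 2. The lowest bin holds 590 and 591 loci, each bin from 10% to 70% holds under 100, and the bins from 70% up hold 766 and 389, 2510 and 2757, and 154 and 300, so that replicate 2 lies higher at methylated loci.

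Most protein-coding genes were lowly methylated, a smaller part carried gene body methylation and a small set exceeded the average gene in CHG or CHH. This set is named TE-like because transposons are methylated in these contexts, but its members need not reach transposon levels. Of 26339 genes tested, 17563 (66.7%) were unmethylated, 5714 (21.7%) gene body methylated and 1615 (6.13%) TE-like in both libraries. A further 1236 genes changed class between libraries and 211 were intermediate. Gene body methylated genes had CG at 29.8% ± 0.173 with CHG at 0.675% ± 0.00769, and a median length of 3455 bp against 1839 bp in unmethylated genes. TE-like genes stood at 31.8% ± 1.03 in CG, 13.5% ± 0.295 in CHG and 3.84% ± 0.0672 in CHH. These pooled values give weight to a few genes of very high depth, and without cytosines over 100 reads, an alternative chosen after seeing the data, they were 40.0% ± 0.186, 16.7% ± 0.282 and 3.85% ± 0.0965. In pericentromeres 27.6% ± 0.215 of the genes were TE-like, against 3.93% ± 0.0616 in arms. The TE-like genes of highest CHG were AT5G18636 (73.8% ± 4.60), AT2G22440 (72.5% ± 2.11), AT1G27870, AT5G36228, AT4G28870, AT2G14265, AT1G62895, AT1G48953, APD3 (AT2G38220, 68.7% ± 0.196) and AT3G54730, with CHH from 10.8% to 30.9%. The gene body methylated genes of highest CG were AT2G04063 (94.1% ± 0.857), AT5G35688, AT2G04622, AT3G30247 and AT2G23945 (76.6% ± 2.12), 4 of them in pericentromeres. These 4 were short, from 334 to 551 bp. Mean CHG was 5.30% ± 2.79 in AT2G04622, 3.56% ± 0.0747 in AT5G35688 and 2.10% ± 1.27 in AT2G04063, above the average gene although the CHG test was not passed. It was 1.57% ± 2.22 in AT3G30247 and 1.04% ± 0.323 in AT2G23945. Membership of this class thus does not show that CHG methylation is absent.

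Genes of the DNA methylation list, most of which encode the machinery that writes, reads or removes the mark, were often gene body methylated. Of 31 classified genes, 20 (64.5%) were in that class against 22.7% of other genes (2-sided Fisher's exact test, adjusted p = 5.40e-06). The comparison was not matched for gene length. Gene body methylated genes had a median of 3455 bp and unmethylated genes 1839 bp, so the test does not separate list membership from length. The highest CG levels were in DCL3 (54.7% ± 0.238) and RDR2 (53.2% ± 0.177), which make the small RNAs of RNA-directed methylation, and in NRPD1 (48.9% ± 1.31), the largest subunit of RNA polymerase IV. NRPB1, the corresponding subunit of RNA polymerase II, which α-amanitin inhibits, stood at 48.8% ± 0.580. IBM1, a histone demethylase that protects genes from CHG methylation, and SHH1 were TE-like, with CHG at 3.69% ± 0.550 and 2.60% ± 0.220. Chosen after their values were seen, the maintenance methyltransferases MET1 and CMT3 were in the unmethylated class, with CG at 5.84% ± 1.36 and 8.17% ± 0.606, and the remodeller DDM1, at 15.4% ± 1.04, changed class between libraries.

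Imprinted endosperm genes and known epiallele loci were enriched in the TE-like class, which requires only CHG or CHH above the average gene. Of 20 classified imprinted genes, 9 (45.0%) were TE-like against 6.40% of other genes, and of 15 epiallele loci 8 (53.3%) against 6.41% (2-sided Fisher's exact tests, adjusted p = 5.40e-06 for each). The MADS-box genes AGL36 and AGL92 were methylated at 86.9% ± 1.54 and 83.6% ± 2.15 in CG and 35% ± 0.399 and 37.5% ± 0.726 in CHG, and AGL28 at 54.1% ± 2.96 and 8.82% ± 0.232. HDG9 and MYB3R2 had CG levels of 13.7% ± 1.99 and 16.8% ± 1.15, with CHG at only 3.88% ± 0.501 and 8.46% ± 0.634. Chosen after their values were seen, the TE-like genes HDG3 and YUC10 had CHG at 2.82% ± 0.0454 and 3.52% ± 0.757. In CG, HDG3 was at 1.11% ± 0.0127. Among epiallele loci, the resistance genes RPP7 and RPP4 stood at 55.4% ± 0.966 and 57.2% ± 3.16 in CG and 39.6% ± 1.62 and 33.2% ± 3.06 in CHG, and SNC1 and RPP5 of the same family as RPP4 at 14% ± 0.258 and 13.1% ± 0.830 in CG. In CHG, SNC1 and RPP5 were at 3.18% ± 0.212 and 5.18% ± 0.398. FWA, a homeodomain gene silenced by methylation of its promoter repeats, had CG at 18.3% ± 0.0120 over the gene. Its CHG was at 1.25% ± 0.282 and its CHH at 1.70% ± 0.0876. FWA and SDC stand in both lists, IBM1 and ROS1 in the methylation and epiallele lists, and AG, SUP and FLC in the epiallele and developmental lists, so these tests are not independent. The following 4 genes were also chosen after their values were seen. The TE-like genes SDC and QQS stood at 7.63% ± 0.594 and 12.5% ± 1.74 in CG and 5.25% ± 0.972 and 5.76% ± 0.543 in CHG. MEA and FIS2, Polycomb genes expressed from the maternal allele in endosperm, were in the unmethylated class. Their CG levels were 0.379% ± 0.218 and 0.721% ± 0.0160.

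Developmental regulators were unmethylated. All 13 genes of that list were in the unmethylated class, with a median CG level of 0.678% ± 0.204 and a range from 0.309% to 2.10%, the latter in the meristem gene STM. The lowest was the floral gene SUP, chosen after its value was seen. The flowering repressor FLC was at 1.27% ± 0.0802, and PI, LEC1, LEC2 and AP3 lay between 0.668% and 0.755%. The absence of gene body methylated members had an adjusted p of 0.123 (2-sided Fisher's exact test, unadjusted p = 0.0493), which did not pass the threshold. Of 14 housekeeping genes, 11 were unmethylated and 3 gene body methylated (PP2AA3 at 32.9% ± 0.151, SAND at 21.7% ± 2.39 and ACT7 at 19.3% ± 3.51 in CG), a share that did not pass the threshold against other genes (Fisher's exact test, adjusted p = 1). Of the 10 list tests, 3 passed.

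CHH methylation at pseudogene loci depended on the bases after the cytosine. CTA and CAA were highest, at 18.5% ± 0.169 and 18.3% ± 0.175, while CTC, CTT, CAC, CAT and CCA lay between 5.52% ± 0.0394 and 2.98% ± 0.0195. CCT and CCC were lowest at 1.11% ± 0.00918 and 0.959% ± 0.00833, and CTA exceeded CCC by 17.5 ± 0.177 points. In CHG, CCG stood at 21.5% ± 0.410, below CAG at 38.8% ± 0.629 and CTG at 39.1% ± 0.713. In pericentromeres CAA was at 11.3% ± 0.0869 and CTA at 10.5% ± 0.124, and in arms at 1.70% ± 0.0154 and 1.40% ± 0.0214. CMT2 is known to act on CAA and CTA sites and CMT3 on CAG and CTG more than CCG.

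The 5 chromosomes were read at nearly the same depth. The median depth of 100 kb windows per chromosome, relative to the genome, lay between 0.987 ± 0.00941 on chromosome 2 and 1.01 ± 0.00201 on chromosome 3. After the haploid and colchicine steps in the history of the line, the comparison bears on gain or loss of single chromosomes. It cannot give the number of whole chromosome sets, as each value is relative to the genome. ONSEN copies had a median relative depth of 0.380 ± 0.00469, below the 0.818 ± 0.0231 of all pseudogene loci, from 0.256 ± 0.00603 in AT1G58140 to 0.929 ± 0.0499 in AT1G48710. The median 100 bp window inside AT1G11265 and AT3G61330 had 0 reads in both libraries. Depth was uneven within a copy, as 200 bp of AT1G11265 (chromosome 1, 3782101 to 3782300), within the span of AT1G11270, were at 5.85 ± 0.238 times the median window with CG at 83.0% ± 1.44. Where reads of near-identical copies were dropped, depth does not give the number of copies. Of the other mobile elements, CACTA1 (AT2G12210) stood out, with a relative depth of 1.54 ± 0.00790, and its median window was at 1.74 ± 0.0463 against 0.765 ± 0.0856 and 0.577 ± 0.0660 in the flanks on either side.

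Of the 10 loci of highest relative depth, 6 lay in pericentromeres and 2 at the start of chromosome 2, next to an array of ribosomal RNA genes. After AT3G41762, they were AT2G01008 (192 and 158 times the median gene in replicates 1 and 2) and AT2G01023 on chromosome 2, then AT2G08986, AT1G40104, AT2G07981, AT2G16586, CYP96A3, AT2G07688 and AT4G06700. CYP96A3 (AT1G65340), a cytochrome P450 gene in the arm of chromosome 1, was the only one with CG under 1% (0.552% ± 0.0685), and it had a relative depth of 19.9 and 18.4. Depth of at least 4 times the median window ran over 2800 bp (chromosome 1, 24267401 to 24270200, TAIR10), at 20.3 ± 1.5 times. Under this cutoff, the stretch begins 81 bp upstream of the start codon of PHE1, the imprinted MADS-box gene next to it. The adjoining 100 bp window, which holds the start codon, was already at 3.67 and 3.19 in replicates 1 and 2. The PHE1 gene outside the windows next to the stretch was at 1.17 ± 0.116. Chosen after the values were seen, RANGAP1 (AT3G63130) had a stretch of 300 bp (chromosome 3, 23325101 to 23325400) at 7.08 ± 0.798 times the median window. The window after it was at 3.06 and 2.56 in replicates 1 and 2. Outside the stretch and the windows next to it, RANGAP1 was at 1.26 ± 0.239. In chromosome arms, 10 such segments, among them that in AT1G11265, of at least 4 times the median in both libraries overlapped 7 of 24269 protein-coding genes, under a criterion also set after the depth had been examined.

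**Figure D5:**
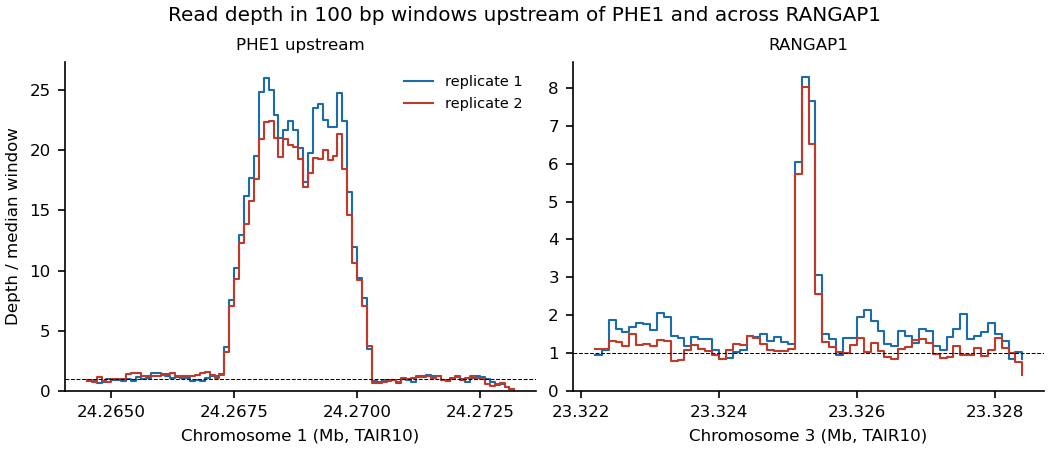
Depth of 100 bp windows over the median window (y axes, different scales) along chromosome 1 upstream of PHE1 and along chromosome 3 across RANGAP1 (x axes, Mb, TAIR10), in replicate 1 and replicate 2, with the dashed line at 1. The raised stretch spans 2800 bp at 20.3 times the median on the left and 300 bp at 7.08 times on the right.

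The libraries were close to each other, and large differences were few. Across 100 bp windows, which are not independent, Pearson's r between replicates was 0.991 in CG, 0.971 in CHG and 0.909 in CHH. In CG, 903 of 677933 windows differed (559 higher in replicate 1 and 344 in replicate 2). In CHG 204 of 734858 differed (144 and 60), and in CHH 1443 of 1173512 (659 and 784). Over whole loci, 2533 of 30645 differed in CG by Fisher's exact test (998 higher in replicate 1 and 1535 in replicate 2), 71 of them by at least 10 points. The chi-square per locus had a mean of 2.74 and a median of 0.988, values that calls on shared fragments also raise, so they do not show whether the pools came from separate plants. The largest difference was at AT1G64795 on chromosome 1, with CG at 61.7% in replicate 1 and 20.5% in replicate 2. AT3G05725 (59.6% and 33.5%), AT1G77820 (59.1% and 35.6%), AT1G53265, AT5G35945, AT4G04693, AT2G32291 and AT3G45920 were also higher in replicate 1, and AT5G28515 (68.1% and 90.9%) and AT2G11460 (76.6% and 90.7%) in replicate 2. The test compares these 2 libraries and not conditions. With the calls of 1 cytosine per window, which keeps a median of 16 calls, 775 CG windows and 1 CHG window passed, and 0 in CHH by Fisher's exact test, where 1609 had an unadjusted p under 0.05 and the minimum difference. The window counts also changed by over 1.5 times with 200 bp windows in CG (399 of 499354) and CHH (502 of 587880), where fewer windows were tested. In CHG, 238 of 510509 such windows differed. With no minimum difference, counts also rose by over 1.5 times, to 4373 in CG and 3536 in CHH. Of these CG windows, 2237 were higher in replicate 1 and 2136 in replicate 2.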

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

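The alternatives without cytosines over 100 reads, with the housekeeping CHH level subtracted, and with 1 cytosine per window were chosen after seeing the data. The other alternatives were planned. For the 48 main results, 208 alternatives were computed: 152 stayed within the spread between replicates, or for counts within 1.5 times, 56 moved (22 up, 34 down) and 0 changed sign. Levels, shares, counts and depths cannot be negative, so only differences, and levels with a background subtracted, could change sign. Of the tests of gene lists, 0 gained or lost their call, while calls of single windows were lost as given below. All 90 values from a single library stayed within that spread, which for a mean of 2 libraries follows from the arithmetic. Of 150 alternatives for 30 single loci and lists, 102 stayed and 48 moved (11 up, 37 down). The chloroplast background, and with it the organelle levels and the subtraction of the chloroplast level, was not run because chromosomes 1 to 5 alone were analysed. No paired analysis was possible because there is a single group.

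With at least 10 reads per site, nuclear levels were 21.3% in CG, 6.16% in CHG and 2.01% in CHH, and the mean of site levels gave 25.1%, 7.74% and 2.24%. Without cytosines over 100 reads they were 21.9%, 6.57% and 1.98%, and with the housekeeping level subtracted 22.2%, 6.18% and 1.52%. The pericentromere minus arms difference was 40.0, 21.9 and 4.26 points with 4 Mb windows, 35.9, 18.3 and 3.71 with at least 10 reads, and 45.7, 21.7 and 3.82 without cytosines over 100 reads. Without these cytosines the CG difference was 40.0, 46.1, 49.9, 44.5 and 47.4 points on chromosomes 1 to 5, so that the low value of 26.4 on chromosome 3 did not hold, and TE-like genes were at 40.0% in CG and 16.7% in CHG. With at least 4 reads the CHH difference was 3.79. Pseudogene loci exceeded protein-coding genes by 56.0, 33.3 and 6.0 points with at least 10 reads, by 60.3, 35.9 and 6.75 as a mean of site levels, and by 58.6 (CG) and 6.44 (CHH) without cytosines over 100 reads. Methylated sites made up 25.5%, 12.6% and 2.69% with at least 10 reads and 28.8%, 12.4% and 1.97% against a fixed 2% background. The cause was not tested. Windows differing between replicates numbered 399 in CG and 502 in CHH with 200 bp windows, 4373 and 3536 with no minimum difference, and 1 in CHG and 0 in CHH with 1 cytosine per window, which leaves fewer calls to test.

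Scaled to genes of the same cytosine content, the median relative depth was 0.374 for ONSEN, 0.516 for the other mobile elements and 0.793 for pseudogene loci, and it was 0.387 for ONSEN from CHH calls alone. Over arms, chromosomes 1, 2 and 3 were at 0.991, 0.997 and 1.01. At a median depth of 13 and 14 calls per cytosine, levels of single sites have wide intervals, and copies with near-identical sequence were not resolved.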

Other observations

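The test of where the WPP codons of RANGAP1 lie was set before its result was seen, and the other tests of explanations in this part were chosen after the results had been seen.

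Sadhu elements, short retroposons known for differing between Arabidopsis accessions in methylation, were mostly either unmethylated or highly methylated in TEmob. They were chosen as a group after the values were seen. Of 16 tested, 8 were under 10% CG in both libraries and 7 above 70%. Unmethylated members included SADHU1-1 in the pericentromere of chromosome 2 (CG 1.25% ± 0.284, SD, n = 2) and SADHU7-1 on chromosome 3 (0.557% ± 0.0505), while SADHU8-1 (96.1% ± 0.507) and SADHU6-1 (93.4% ± 2.24) were methylated. SADHU1-3 stood between them at 49.3% ± 3.78. SADHU5-1 had CG at 2.23% ± 0.527 with CHG at 4.69% ± 0.0973 and CHH at 5.11% ± 0.177, so that both non-CG levels exceeded CG.

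Several longer stretches of chromosome arms, also chosen after their depth was seen, had near 2 times the depth of the median window. The region from YUC11 to SWEET1 on chromosome 1 was at 1.98 ± 0.129, AT1G77930 to AT1G77940 at 2.32 ± 0.0229, AT3G06433 on chromosome 3 at 2.09 ± 0.204 and SEC10 on chromosome 5 at 1.72 ± 0.262. No untreated Columbia-0 library was analysed here, so extra copies in the line are not separated from copies that the reference genome merges.

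The raised depth upstream of PHE1 (20.3 ± 1.5 times the median window) and inside RANGAP1 (7.08 ± 0.798), a pair picked from the 10 arm segments after they were seen, was weighed against its surroundings. Against windows of the same cytosine content the lower of the segments was still at 6.29 or more in both libraries. Windows of that content are thus not raised in general. The segments were picked for high depth, however, so this could not exclude other effects of content. The highest flank of 2 kb was at 1.45, which argues against a duplication of the whole region. This holds only closely, since the bound of 1.5 was set after the profiles were seen. A hypothesis is an inserted construct for INTACT, the nuclear purification method named in the series design, whose nuclear tag carries as background the WPP domain of RANGAP1 and for endosperm is driven by the PHE1 promoter. The single match in RANGAP1 to the codons of the WPP motif began at 23325156 on chromosome 3, inside the raised segment, which covers 12.0% of the gene, and this is consistent with such a construct. Depth was not raised at 2 other genes that were examined. The CENH3 gene was at 1.04 ± 0.0797 times the median window, and ACT2 with 1 kb on both sides at 0.982 ± 0.0608. The hypothesis thus rests on the PHE1 and RANGAP1 segments alone. The site, the number of copies and the ratio of 2.86 between the segments were not explained, and no biological explanation was tested because there is 1 group.

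In unmethylated genes, cytosines followed by A had a higher apparent level than those followed by T, with CAC at 1.21% ± 0.0141 and CTC at 0.433% ± 0.00345. Methylation by the activity seen at pseudogene loci would give CAG and CTG, which face each other on opposite strands, similar levels, but their ratio was 2.00 ± 0.00819 in unmethylated genes and 0.994 ± 0.00204 at pseudogene loci. The CAC minus CTC excess was 0.889 ± 0.0724 points in the 13 developmental genes. In all unmethylated genes, which include these 13, it was 0.781 ± 0.0107. A conversion or calling background that depends on the trinucleotide would give such an excess. Low methylation at CA sites throughout the genome would give it too and stays open, as no sequence known to be unmethylated was analysed here. No other biological explanation was tested.

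At AT1G64795, within the span of ILA, replicate 2 was less methylated over 600 bp (chromosome 1, 24082201 to 24082800), at 29.2% against 76.1% in CG, 16.1% against 60.6% in CHG and 4.36% against 18.1% in CHH. The locus was picked for this difference, and its adjusted p of 1.23e-27 in CG (Fisher's exact test) counts calls on shared fragments as independent. With 1 cytosine per window, the lowest adjusted p in the region by the same Fisher's exact test was 0.0643 (CHG, unadjusted p = 2.61e-07) and 1 in CG, so sampling of reads is not excluded, though the CHG value is close to the threshold. The depth ratio of replicate 2 over replicate 1 was 1.02, where 2.61 would be needed if extra unmethylated copies made the whole difference. This argues against such copies as the only cause, provided that their reads were placed here. A smaller contribution from them is not excluded. A mix of plants and a partial loss in some of them stay open, and no biological explanation was tested because the libraries belong to 1 group.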
